A study of Mus musculus with 2 samples.

How the data were processed

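Back-skin epidermis of mice at postnatal day 5 was compared between animals lacking the vitamin D receptor (VDR, gene Vdr) and the calcium-sensing receptor (CaSR, gene Casr) in keratinocytes, called DKO here, and littermate controls, called CON. Per the labels' protocols, both genes were removed by Cre recombinase driven by the keratin 14 promoter, the control mice carried the same floxed alleles without Cre, epidermis was lifted from dermis with dispase, and RNA of 3 mice per genotype was combined. The tables hold 1 array per group. The design text also gives 3 for each group, which the labels describe as the mice combined into each sample. The protocol text names a VDR knockout where the sample titles name the knockout of both receptors, and the titles and genotypes were followed.

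The arrays were Illumina expression arrays with 25697 probes, read with GenomeStudio 2011.1 per the submitters' processing notes. The authors deposited raw signal intensity per probe, not background-subtracted, with a detection p-value for each probe. They also deposited a table of normalized signal intensity on a linear scale. Per the file headers, array columns are tied to CON and DKO by a line above the column names. The normalization method of that table is not given in the sources used here. Its sorted values on the 2 arrays differ by at most 0.9 signal units, and 99.7% of probes on the CON array and 99.9% on the DKO array lie above their raw value. The values listed for the series as a whole differ from that table at 0 probes, so they are the same measurement on a linear scale. They are not centred, and the median is 149 on each array.

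Values reported here were made from the raw intensity. Background was corrected with limma 3.58.1 in R 4.3.3 (neqc: normexp with parameters taken from the detection p-values, offset 16), followed by quantile normalization and log2. Differences are DKO minus CON on the log2 scale, and a fold is the ratio of the normalized linear signals. A probe counted as detected at a detection p-value under 0.01, a p against the array's own negative controls and no comparison of groups. A gene entered when its main probe, the probe with the highest mean log2 signal, was detected on at least 1 array. Where the dimmer group was not well above background, the fold is a bound, written "at least": the bright signal over the higher of the dim probe's own signal and the lowest signal detected on that array (log2 5.29 on CON and 5.38 on DKO). No fold is given where neither array was above background or the bound is under 1.

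Probes were named from the gene identifiers and accessions in the tables, updated through a RefSeq gene table of assembly GRCm38.p6, which was used only for names and for which genes neighbour each other. Of the 25697 probes, 16938 matched by gene identifier, 7420 by accession, 465 by current symbol and 552 by a unique older symbol, and 322 kept the array's own name. They stand for 17872 genes, 5018 of them with more than 1 probe. Some names differ from those on the array, which lists Casr as Gprc2a, Chil1 as Chi3l1 and Gsdmc as Mlze.

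With 1 array per group there is no replicate check, no test was run and no p-value between groups is given, and the number of arrays limits the precision. The limma test of replicate arrays could not be run. Genes were counted by a fixed rule of size, a difference of at least 2-fold. Named genes are Vdr and Casr, the 15 highest and the 15 lowest genes by log2 difference without unnamed gene models, Xist and Y-linked genes, and up to 4 members of each list with the largest absolute difference. The 29 gene lists cover epidermal layers, junctions, receptor pathways, the hair follicle and other cell types of skin. Of their detected members, 15 genes sit in more than 1 list. Each list's median is given with its percentile among 10000 random lists of the same size, drawn to match mean signal in 20 bins, as a description of these arrays. The groups, the size rule, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

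The steps were tested on simulated data made from the signals of the CON array, with 25697 probes and 200 changed probes. At a true change of 2-fold, 36% of 50 probes passed the 2-fold rule in the right direction, with a median recovered size of 0.96 (log2). At 3-fold 98% passed, and at 4-fold and 8-fold 100% passed. Of the unchanged probes, 2 passed. Changed probes were drawn only from those well above background, so the simulation does not cover dim genes. Added variation between arrays was set to an SD of 0.1 (log2), which leaves out variation between mice. In the data the pooled SD between probes of a gene was 0.30, so the simulated number of unchanged probes that passed does not carry over to these arrays. Alternatives were no background correction, a normexp offset of 50, median scaling in place of quantile normalization, the authors' deposited table, other filters on detection, the mean over probes, quantile normalization without the 20 brightest genes, and other size rules. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.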

Results

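Gene expression was measured in neonatal mouse epidermis at postnatal day 5, on 1 array of combined RNA from 3 control mice (CON) and 1 array of combined RNA from 3 mice lacking VDR and CaSR in keratinocytes (DKO). VDR is the nuclear receptor of active vitamin D, and CaSR is a membrane receptor for extracellular calcium. The series addresses how signalling through both receptors bears on differentiation of the epidermis. On the CON array 10760 of 25697 probes were detected (41.9%), with a median raw signal of 140.5, and on the DKO array 10441 (40.6%), with a median raw signal of 138. There is 1 array per group, so no difference below has a replicate check.

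The knocked-out genes were examined first. All 3 Vdr probes were detected on both arrays, and their log2 differences were -0.12, -0.24 and -0.82. The brightest of them read 10.17 on CON and 10.06 on DKO. The only Casr probe was not well above background on either array, with detection p-values of 0.0338 on CON and 0.941 on DKO, so no fold is given. Where these probes lie relative to the deleted exons is not known from the files, and a probe outside the deleted part checks nothing. The values therefore neither bear out nor contradict the labels.

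Among the 29 gene lists, the hair follicle list had the largest shift of its median and was lower on the DKO array, and the highest named genes included several protease inhibitors of the serpin family. Of 8472 detected genes, 89 were at least 2-fold higher and 118 at least 2-fold lower in DKO, and 8265 (97.6%) lay within 2-fold. With dim values set to their bound, 66 higher and 87 lower genes passed, and 9 higher and 7 lower genes differed by at least 4-fold. Under median scaling the counts at 2-fold were 106 and 106. Genes of the hair follicle list or named as keratin-associated proteins (Krtap) made up 27 of the 118 lower genes (26 of the 87 with bounds) and 0 of the higher ones. The median gene differed by -0.02 on the log2 scale, and the central 95% of genes lay between -0.84 and 0.80. Detected probes of the same gene differed from each other with a pooled SD of 0.30 (log2) over 2047 genes. Among the higher genes 32 were not well above background in CON, and among the lower genes 41 were not in DKO. In the authors' deposited table, whose values carry background, the same rule gave 24 higher and 28 lower genes, and all 24 and 28 were among those counted here.

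**Figure D1:**
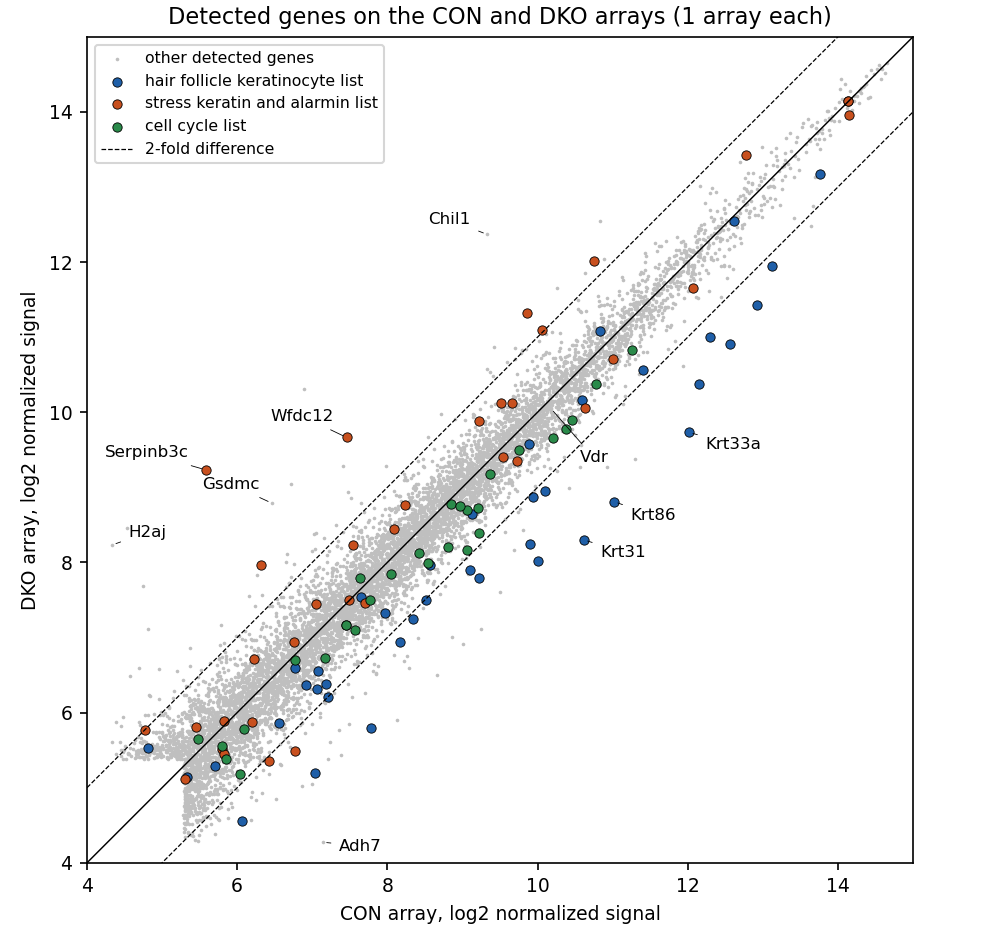
Log2 normalized signal of each of the 8472 detected genes on the CON array (horizontal) and the DKO array (vertical), 1 array per group, with 3 gene lists coloured and dashed lines at a 2-fold difference. Of the 41 detected hair follicle genes, 38 lie below the line of equal signal, while Serpinb3c and Wfdc12 of the stress list lie far above it.

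Among the 15 highest genes, Serpinb3c, a serpin of the clade that inhibits cysteine and serine proteases, was 12.6-fold higher in DKO, and the related gene Serpinb3d was at least 3.57-fold higher. Chil1, a secreted chitinase-like protein, was 8.21-fold higher and read 12.37 (log2) in DKO. Gsdmc, a member of the gasdermin family of pore-forming proteins, was 5.01-fold higher, and its 2 probes above background on both arrays differed by 2.25 and 2.33 (log2). Acoxl, a gene related to acyl-coenzyme A oxidases, differed by 2.32 (log2), the protease inhibitor gene Wfdc12 was 4.61-fold higher, the serine protease gene Prss27 3.69-fold, Serpina3b 3.30-fold, the cornified envelope precursor Sprr2d 3.14-fold and the cytochrome P450 gene Cyp2b23 2.95-fold. H2aj, a histone H2A variant, was at least 7.71-fold higher, Fetub, a secreted protein of the cystatin superfamily, at least 5.29-fold, the kallikrein gene Klk1b22 at least 2.48-fold, Crygn at least 2.45-fold and Epm2aip1 at least 2.31-fold. CON was not well above background for these last 5 genes and Serpinb3d. The other detected probes of Epm2aip1 were above background only on CON, and those of Prss27 reached down to 0.56.

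Among the 15 lowest genes, the hair keratin genes Krt31, Krt33a and Krt86 were 4.97-fold, 4.87-fold and 4.61-fold lower in DKO, and Krt82 was 3.96-fold lower. The keratin-associated protein genes Krtap1-4, Krtap26-1 and Krtap13-1, which encode matrix proteins of the hair shaft, were 4.66-fold, 4.46-fold and 3.70-fold lower. A probe that keeps the array's older keratin name Krt2-18 was 4.41-fold lower, Psors1c2 3.96-fold, Vsig8 3.77-fold and Calhm4 3.60-fold. Genes of metabolism among the lowest were Gnmt, glycine N-methyltransferase, which was 4.28-fold lower, Pcca, a subunit of propionyl-coenzyme A carboxylase, which was 3.84-fold lower, and Adh7, an alcohol dehydrogenase that oxidises retinol, which was at least 3.38-fold lower. Dctn1, a subunit of dynactin, was at least 3.07-fold lower. DKO was not well above background for Adh7 and Dctn1.

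**Figure D2:**
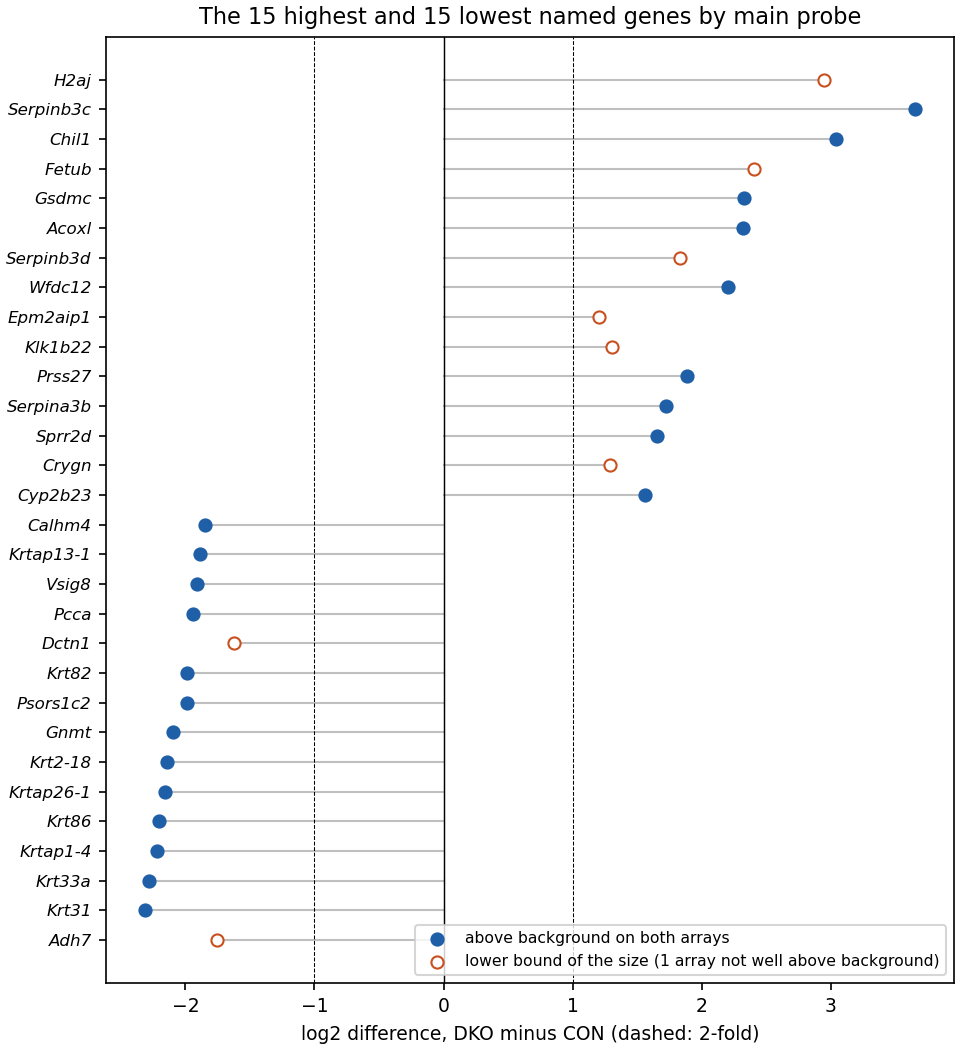
Log2 difference, DKO minus CON, of the 15 highest and 15 lowest named genes by main probe, ordered by measured difference, with 1 array per group. Filled points were above background on both arrays, open points mark the lower bound of the size for the 8 genes not well above background on 1 array, and the values run from 3.65 for Serpinb3c to -2.31 for Krt31.

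The pools also differed in sex-linked transcripts. The brightest probe of the Y-linked gene Ddx3y read 6.89 (log2) on CON and 10.31 on DKO, 10.7-fold higher, and Eif2s3y read 8.46 on DKO and was not well above background on CON. The Xist probes differed by -0.24 and -1.21. These values stand beside every gene group below, since each group was measured on the same pair of pools.

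Hair follicle genes were lower as a group. Of 41 detected members of the list, 20 were at least 2-fold lower (19 with dim values at their bound), 0 were at least 2-fold higher, and 38 were lower by any amount. The median log2 difference was -0.999, lower than that of all 10000 random lists, and -0.84 with dim values set to their bound. Hair shaft keratins had a median of -1.78 with dim values at their bound, where 8 of 9 detected genes were at least 2-fold lower, and inner root sheath keratins such as Krt71 (-1.49) and Krt73 (-1.29) had a median of -1.29 with 5 of 5 at least 2-fold lower. Keratins of the outer root sheath, companion layer and upper follicle had a median of -0.33 with 0 of 4 at least 2-fold lower. Krt75 differed by -0.74, Krt79 by -0.58, Krt23 by -0.07 and Krt17 by 0.01. Krt17 and Krt79 read 14.13 and 13.76 (log2) on CON, and whether such bright signals understate differences was not tested. This grouping of keratins was made after the values were seen. Sox9, a transcription factor of follicle stem and progenitor cells, differed by -1.09, and Hoxc13, a transcription factor of the hair shaft, by -0.999. The melanocyte list, whose cells sit in the hair bulb and epidermis, had a median of -0.38 over 8 detected genes (percentile 0.380), with 7 of 8 lower, 0 of them by 2-fold. Its examples were Gpnmb (-0.94), Ednrb (-0.71), Pmel (-0.61) and Mlana (-0.47), though the other detected probes of Gpnmb and Pmel differed by -0.15 and 0.26, and the median was -0.24 when all detected probes of a gene were averaged. The sebocyte list had a median of -0.05 over 14 genes (percentile 32.5), with Dgat2 at 0.69, Scd1 at -0.40, Plin2 at -0.38 and Pparg at -0.35.

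**Figure D3:**
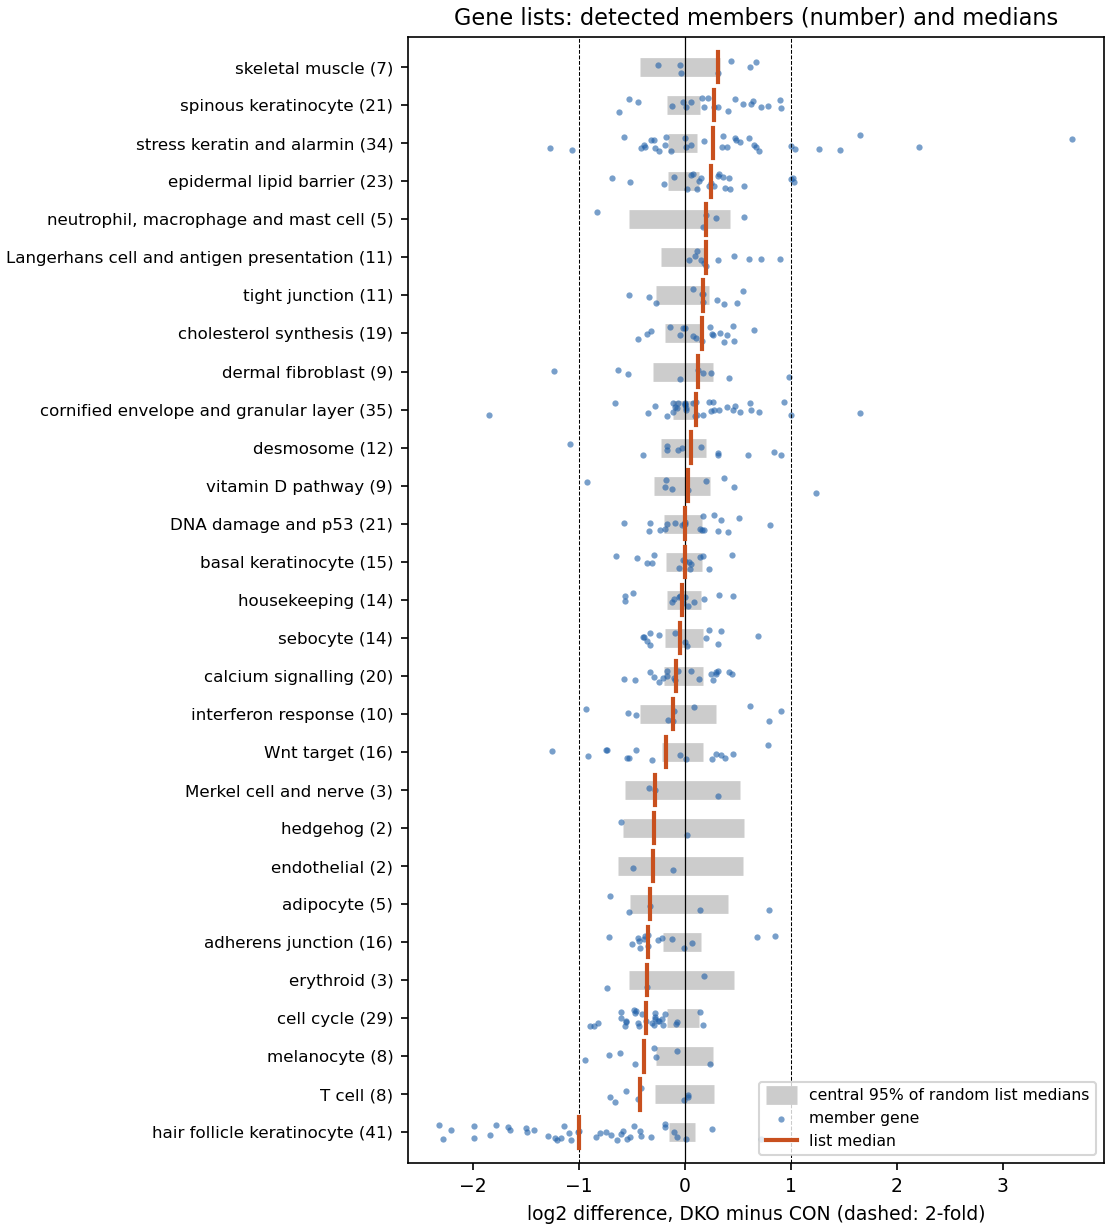
Log2 differences, DKO minus CON, of the detected members of 29 gene lists (points, spread vertically only for display), with list medians (orange bars) and the central 95% of medians of 10000 random lists of matched size and signal (grey). The hair follicle median of -0.999 lies farthest from its random range, which runs from -0.15 to 0.09.

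Genes of the differentiated layers of the interfollicular epidermis were mostly higher on the DKO array, nearly all by less than 2-fold. The spinous list had a median of 0.28 over 21 genes, above all 10000 random lists, with 16 higher, 0 of them by 2-fold. The desmosomal cadherin gene Dsc1 differed by 0.91, the cyclooxygenase gene Ptgs1 by 0.90 (its other probes by 0.86 and 0.11), Serpinb2 by 0.79 and the transcription factor gene Grhl3 by 0.72, whereas Mt4, Krt77 and involucrin (Ivl) differed by -0.62, -0.52 and -0.44. The cornified envelope and granular layer list had a median of 0.10 over 35 genes (percentile 97.9), with 23 higher and 11 lower, among them 1 gene, Sprr2d, at least 2-fold higher and 1 at least 2-fold lower. The latter was Padi3, a peptidylarginine deiminase active in the follicle and the granular layer, at least 2.80-fold lower and not well above background in DKO. Transglutaminase 3 (Tgm3) differed by 0.94, and loricrin (Lor) by -0.07. The spinous median was 0.16 without background correction, and the cornified median was 0.16 with median scaling, 0.083 in the authors' deposited table, 0.087 without the filter on dim probes and 0.078 without members shared with other lists.

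Genes of the epidermal lipid barrier were higher. Their median was 0.25 over 23 genes (percentile 99.9), with 19 higher, 3 of them at least 2-fold, and 0 at least 2-fold lower. The 3 were Aloxe3 (2.04-fold) and Alox12b (2.003-fold), which encode successive lipoxygenases that act on linoleate-containing ceramides of the barrier, and Degs2 (2.03-fold), a sphingolipid desaturase and hydroxylase. All lie at the edge of the size rule. The cholesterol synthesis list had a median of 0.16 over 19 genes (percentile 98.1), with 12 higher, 6 lower and 0 at 2-fold, and examples were Dhcr7 (0.65), Ebp (0.46), Mvd (0.45) and Stard4 (-0.44). The list's median was 0.104 without background correction, 0.109 in the authors' deposited table and 0.23 when all detected probes of a gene were averaged.

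The stress keratin and alarmin list had a median of 0.26 over 34 genes (percentile 99.98), with 6 genes at least 2-fold higher and 2 lower. The 6 were Serpinb3c (3.65), Wfdc12 (2.21), Sprr2d (1.65), Stfa2 (1.46), Serpinb3a (1.26) and Serpinb3b (1.04). Stress-associated keratins lay within 2-fold, where Krt6a differed by 0.06, Krt6b by -0.37 and Krt16 by 0.61, and the alarmin genes S100a8 and S100a9 differed by -0.13 and -1.27. S100a9 and Sprr2a1 were the 2 lower genes. The list's median was 0.06 without the members it shares with other lists, and 0.10 without background correction.

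Cell cycle genes were lower, none by 2-fold. Their median was -0.37 over 29 genes, lower than that of all 10000 random lists, with 27 of 29 lower. Mcm2 and Mcm5, subunits of the replicative helicase, differed by -0.89 and -0.60, and Nusap1, a spindle protein, by -0.82. Pcna differed by 0.17. The list's median was -0.22 in the authors' deposited table. The hair follicle list, whose bulb holds dividing cells, was lower on the same arrays, with a median of -0.999 and 38 of 41 genes lower. The basal keratinocyte list had a median of 0.00 and a mean of -0.07 over 15 genes (percentile 55.3), with Krt14 at 0.00, Krt5 at 0.04, Igfbp5 at -0.65 and Itga6 at -0.45.

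Adherens junction genes were lower, none by 2-fold. Their median was -0.35 over 16 genes (percentile 0.030), with 13 lower. E-cadherin (Cdh1) differed by -0.50 and the phosphoinositide 3-kinase regulatory subunit gene Pik3r1 by -0.71, while Nectin4 differed by 0.68. The desmosome list had a median of 0.06 over 12 genes (percentile 76.6). In it Pkp2 was 2.11-fold lower by its main probe, with another probe at -0.75 and a further one dim in DKO, and Dsc1, Jup and Dsc3 differed by 0.91, 0.84 and 0.59. The tight junction list had a median of 0.17 over 11 genes (percentile 93.3), with Cldn23 at 0.55 and Cldn3 at -0.53.

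Lists for the pathways of the removed receptors lay within the range of random lists. The vitamin D pathway list had a median of 0.03 over 9 detected genes of 20 on the array (percentile 67.7). Detected members included Vdr, Rxra, Rxrb, Ncoa1, Med1 and Med24, but not Cyp24a1, S100g or Camp. Little about transcription driven by VDR can therefore be read from this list. In it the pattern recognition receptor gene Tlr2 was 2.35-fold higher, the calcium channel gene Trpv6 differed by 0.46, and Med1, a Mediator subunit that binds VDR, differed by -0.92. The calcium signalling list had a median of -0.08 over 20 genes (percentile 25.4), with Src at -0.57, Atp2a3 at -0.47, Atp2c1 at 0.45 and Itpr2 at 0.42. The Wnt target list had a median of -0.18 over 16 genes (percentile 5.42), and -0.024 with dim values at their bound. Among its members were the Wnt ligand genes Wnt3 (0.78), Wnt10b (0.38), Wnt10a (0.34), Wnt4 (0.30) and Wnt5a (-0.52) and the receptor gene Fzd10 (0.26). The median therefore does not describe targets alone in this list. In it Nkd2, an inhibitor of the Wnt transducer Dishevelled, was 2.38-fold lower, and cyclin D1 (Ccnd1) differed by -0.91 with all detected probes between -0.91 and -0.69. Of the hedgehog list only Smo (-0.61, other probes -0.71 and 0.04) and Shh (0.03) were detected, and the median was -0.29 (percentile 14.1).

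Among markers of other cell types, T cell genes were lower, with a median of -0.43 over 8 genes (percentile 0.200), 6 lower and 0 at 2-fold. Lck differed by -0.70, Nkg7 by -0.65, Thy1 by -0.55 and Cd3e by -0.44, whereas Cd3d and Cd3g both differed by 0.03, and the list's median was 0.01 without the filter on dim probes. The Langerhans cell and antigen presentation list had a median of 0.20 over 11 genes, all 11 higher (percentile 96.9), with the Langerhans cell lectin gene Cd207 at 0.60 and H2-Aa at 0.47. Medians were 0.20 for the neutrophil, macrophage and mast cell list (5 genes, percentile 85.1), 0.13 for dermal fibroblasts (9 genes, percentile 85.8, mean -0.06), 0.31 for skeletal muscle (7 genes, percentile 96.4), -0.32 for adipocytes (5 genes, percentile 12.6, -0.003 with bounds), -0.30 for endothelium (2 genes, percentile 15.3), -0.35 for erythroid cells (3 genes, percentile 9.93, -0.19 with bounds) and -0.28 for Merkel cells and nerve (3 genes, percentile 18.2, -0.13 with bounds). Of these only Mgp, a matrix calcification inhibitor in the fibroblast list, passed the size rule, at 2.35-fold lower.

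The interferon list had a median of -0.11 (-0.053 with dim values at their bound) and a mean of 0.01 over 10 genes (percentile 46.6), and the DNA damage and p53 list a median of 0.00 over 21 genes (percentile 60.3), with Ddb2 at 0.80 (its other probes at 0.77 and 0.085) and Bax at -0.58. Housekeeping genes had a median of -0.03 over 14 genes (percentile 35.3), and 0 of them passed the size rule. Within that list the probes of Actb disagreed, with differences from -0.57 to 0.53. In all, 10 of the 29 lists had a median outside the central 95% of random lists. The cornified and cholesterol lists passed narrowly, at 0.102 (percentile 97.9) and at 0.163 against an upper limit of 0.155. Several alternatives put either median under its upper limit. Others also fell inside: the stress list (0.062 without shared members, limit 0.116) and the T cell list (0.010 without the filter on dim probes, limit -0.285). The melanocyte list did so at -0.235 with probes averaged (limit -0.275). All limits were drawn under the main setting, and values that carry background have smaller ratios, so these comparisons are rough.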

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

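The bound on dim values, the requirement that every probe pass, and the removal of chromosomes were tests chosen after the results were seen, and the other alternatives were planned. The 30 genes with the largest differences kept their sign under each alternative in which they remained. Of these, 21 stayed at least 2-fold apart in each. Those not well above background in CON or DKO drop out when both groups must be detected. All alternatives reuse the same 2 arrays from which the 30 genes were picked, so a kept sign is weak support. Of 1295 alternative values of named genes, 1069 lay within the spread between probes of a gene, 226 moved further and 0 changed sign among genes that passed the size rule. Of the list medians, 166 alternative values of lists inside the random range stayed within the SD of random medians and 14 moved further. The hedgehog, endothelium, erythroid, and Merkel cell and nerve lists, with few detected genes, were left out of this count. For the 10 lists outside the random range 90 stayed and 30 moved. The counts of genes at least 2-fold higher and lower, 89 and 118, became 66 and 87 with dim values at their bound, 106 and 106 with median scaling, 23 and 27 without background correction, 43 and 58 with an offset of 50, and 24 and 28 in the authors' deposited table and in the identical values listed for the series. Those values carry background, which shrinks ratios by construction. The counts were 57 and 77 when both groups had to be detected, 516 and 624 at 1.5-fold, 16 and 27 at 3-fold, and 8 and 6 when at least 2 detected probes all had to pass, all of which change the genes or sizes admitted.

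The hair follicle median was -0.70 without background correction, -0.81 with the larger offset, -0.74 in the authors' table and the series values, -0.70 without the filter on dim probes, -0.84 with dim values at their bound, and -0.92 without the chromosomes of Vdr and Casr. The cell cycle median was -0.22 without background correction, -0.28 with the larger offset, -0.22 in the authors' table and the series values, and -0.28 without the filter. The stress and alarmin median was 0.10 without background correction, 0.17 with the larger offset, 0.12 in the authors' table and the series values, 0.063 without the filter, 0.35 with both groups detected, 0.35 without the chromosomes of Vdr and Casr, and 0.062 without members shared with other lists. The spinous median was 0.16 without background correction and 0.175 in the authors' table and the series values, the cornified median 0.16 with median scaling, 0.083 in the authors' table and the series values, 0.087 without the filter and 0.078 without members shared with other lists, the cholesterol median 0.104 without background correction, 0.109 in the authors' table and the series values, 0.136 without the filter, 0.142 with median scaling and 0.23 with probes averaged, the adherens junction median -0.25 without the filter, and the melanocyte median -0.235 with probes averaged. The T cell median was -0.19 without background correction, -0.23 in the authors' table and the series values, and 0.01 without the filter, a change of sign. The cause of these shifts of medians was not tested. No paired analysis was possible because each group has 1 array, and for the same reason the test of replicate arrays, a replicate block and leaving out replicates were not run. Signal over background limits the dim genes: 32 of the higher and 41 of the lower genes have only a bound. At their bound the hair follicle list kept 19 of its 20 genes at least 2-fold lower, and the medians of the Wnt, adipocyte, erythroid, Merkel cell and nerve, and interferon lists were -0.024, -0.003, -0.19, -0.13 and -0.053.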

Other observations

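The families, neighbours and probe comparisons in this part, and the tests with sebocyte genes, with the chromosome of Vdr, with S100a8 and S100a9, with second probes and with the other shaft keratins, were chosen after the results were seen. The tests with melanocyte genes, abundant follicle genes, normalization settings and neighbours of Casr were written before their results were seen.

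Several gene families encoded in clusters were higher together on the DKO array. All 4 detected Serpinb3 genes were at least 2-fold higher, whereas of 4 detected Serpinb6 genes only Serpinb6d was, at 1.49 (log2), with a median of 0.52 and Serpinb6a at -0.37. Of 3 detected Cyp2b genes, 2 were at least 2-fold higher, Cyp2b23 at 1.56 and Cyp2b19, a keratinocyte epoxygenase, at 1.39. The kallikrein proteases (Klk) had a median of 0.63 with 8 of 9 genes higher, 1 of them by 2-fold. Skint genes, relatives of the selection element of epidermal gamma delta T cells, had a median of 1.04 over 3 genes. The directions of these medians held under each of the 5 normalization or background settings, where the lowest were 1.09 for Serpinb3, 0.38 for Serpinb6, 0.85 for Cyp2b, 0.40 for Klk and 0.47 for Skint. The clustered Lce1 and Lce3 genes did not move so, with a median of 0.045 over 14 genes and 0 at 2-fold. Other higher genes were Ptges, prostaglandin E synthase, at 1.44, Igfbp3 at 1.46, Socs3, a feedback inhibitor of cytokine signalling, at 1.14, and Chit1, a chitinase, at 1.25.

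Lower genes outside the follicle list included the gluconeogenic enzyme gene Fbp1 at -1.71, the transporter gene Slc6a13 at -1.81, Agpat2 of phospholipid and triglyceride synthesis at -1.53, xanthine dehydrogenase (Xdh) at -1.33 and the basal-cell transcription factor gene Bnc1 at -1.50. Alcohol dehydrogenase genes moved apart, with Adh1 at 1.45 and Adh7 at least 3.38-fold lower. Of 48 detected histone genes, 4 H2A genes were at least 2-fold lower, H2ac10 (-1.31), H2ac21 (-1.18), H2ac24 (-1.15) and H2ac22 (-1.03), and H2aj alone was higher by that much. Every detected H2ac gene was lower, the least being H2ac18 (-0.015), whereas every detected H2bc gene except H2bc3 (-0.41) was higher. The cause of this split was not tested. Of 4 detected Ly6g6 genes, Ly6g6d and Ly6g6g were at -1.65 and -1.52. Mitochondrial ribosomal protein genes had a median of 0.01 over 68 genes. Of 22 detected Krtap genes, 8 were at least 2-fold lower, but the median was -0.60 (-0.33 without background correction and -0.38 in the authors' table) and 6 were higher, up to 0.62.

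The lower hair follicle list is not explained by the choice of normalization or background correction, since the median nearest 0 under any such setting was -0.70. The 32 members on other chromosomes than Vdr had a median of -0.75. Variation linked to the Vdr locus does not account for them if it acts only on genes of its own chromosome. A linked variant in a regulator could act on members elsewhere, and this test cannot exclude that. The 9 members on Vdr's chromosome had a median of -1.49, and 6 were at least 2-fold lower (5 at their bound) against 14 of 32 elsewhere. Shaft and inner root sheath keratins there differed from those elsewhere by -0.028 in median, short of the 0.5 set either way, so that test decides nothing. Per the labels, the littermate controls carried the same floxed alleles without Cre. The design thus argues against variation linked to Vdr that differs between the groups, although flanking sequence was not examined. Loss of whole pilosebaceous units as large as the hair follicle median of -0.999 is argued against by the sebocyte median of -0.046. The lowest sebocyte member, Scd1, was at -0.40. Interfollicular epidermis also expresses some members such as Fabp5, and the gland genes Awat2 and Mc5r differed by -0.24 and 0.20, so a smaller loss of these units stays open. Loss of hair bulbs during separation stays open, because the melanocyte median of -0.38 fell between the -0.5 set for it and the -0.2 set against it. For a lower share of all follicle cells alike, 76.9% of the 26 abundant members were lower by at least 0.5, which does not decide it. Their differences ran from 0.255 to -2.314 with an SD of 0.71, against a pooled SD of 0.30 between probes of a gene. This argues against an equal fall of all these members. Members also expressed outside the follicle would fall less, so for follicle cells alone a shared fall stays open. An effect of genotype on hair shaft and inner root sheath differentiation may account for the pattern too, but it was not tested, and with 1 pool per genotype it cannot be told apart from a difference between pools in hair bulbs or in sex.

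Stefin genes, which encode cysteine protease inhibitors, lie next to Casr in the gene order of GRCm38.p6, with Stfa3 adjacent to it and Stfa2 the protein-coding gene after that. Of 7 detected stefin genes 6 were higher, with Stfa2 at 1.46, Stfa3 at 0.65 (its other probe at 1.44) and Stfa1 at -0.18. RNA from neutrophils is argued against as the source, since the higher of the differences of their abundant transcripts S100a8 and S100a9 was -0.13. Both genes also stand in the stress keratin and alarmin list, so RNA of keratinocytes could mask a change in neutrophils. The neutrophil, macrophage and mast cell list had a median of 0.20 over 5 genes, 4 of them higher, so macrophages as a source are not settled. The 5 were Cd68, C1qb, Fcgr3, Csf1r and Cpa3. Neutrophil genes of the list such as Ngp, Ltf and Elane were not among them, so this median says little about neutrophils. Linked variation that changes many genes over a wide region around Casr is argued against as well. Of 93 measured neighbours that are not stefins 1.08% were at least 2-fold apart, where 2.44% of all genes were. The sign of a linked effect had been set at 7.33%. An exact 95% binomial interval ran up to 5.85%. It takes neighbouring genes as independent, holds the 2.44% of all genes, and does not measure variation between mice. An effect of the Casr deletion on its nearest genes alone, or of genotype through another route, may remain, and neither was tested.

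Large differences on an Illumina array can come from a sequence difference under a single probe, but for Gsdmc and Krt86 100% of the 2 other probes above background on both arrays showed over 2/3 of the main probe's difference, which argues against it for these genes. For Gnmt the other probe was dim in DKO, and its bound, at least 2.45-fold lower, is 0.618 of the main log2 difference, under the 2/3 set, so it stays open. For the other 11 genes at least 4-fold apart with dim values at their bound, Y-linked genes aside, no second detected probe exists, so for each gene alone a sequence difference and a change of the gene cannot be told apart. A sequence difference under a single probe would not lower the shaft keratins as a group, Krt31 and Krt33a among them. The 6 others less than 4-fold apart, each with its own probe, had a median of -1.54 with dim values at their bound. These 6 had already been seen to be lower when they were chosen for this comparison. Sequence differences under the probes of several related keratins at once were not tested. The label gives the same strain for both groups, yet with bounds the probes of 2 genes, Mgst1 and Rpl29, differed by at least 2 (log2): 1 probe of each was at least 10.6-fold and 35.1-fold higher, where the other differed by 0.31 and 1.22.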
